A study of Homo sapiens with 12 samples.

How the data were processed

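Polyadenylated RNA of SUM159 mammary carcinoma cells was sequenced in 12 libraries, 2 in each of 6 groups, from cells under standard culture with stably selected vectors. Per the labels' protocols, libraries were made with the KAPA mRNA HyperPrep kit, which marks the strand with dUTP. The deposited files hold whole-number counts of reads per gene, 1 file per library, with Ensembl gene identifiers and no normalization by the authors that the files or labels record. The submitters' processing notes name FastQC, STAR 2.6.1a and the human genome hg38 (GRCh38). The counting tool, the annotation release and the strand setting are not given in the sources used here, so reads of overlapping and antisense genes cannot be told apart with certainty. Replicates came from biological duplicates per the series design, but how the cultures were separated is not stated, and p-values measure only the spread between these libraries.

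Each library lists 58243 gene identifiers, of which 57980 are in GENCODE 29, used here for symbols, GRCh38 coordinates, GC content and transcript length, and 38067 had at least 1 count. Total counts were 26786139 and 24824240 with dKO EV, 29233965 and 26034898 with dKO dNp63, 31707599 and 30870454 with TAp73, and 24017687 and 28807543 with both factors. They were 35899557 and 28776402 with ITGB4-lo EV and 36974577 and 33753597 with ITGB4-lo dNp63. Mitochondrially encoded genes took 3.617% to 4.838% of the counts. Replicates differed by more than sampling noise in every group (chi-square over its degrees of freedom 5.532 to 17.79), so none was a copy of another. The largest values were those of dKO EV (17.79) and ITGB4-lo EV (17.32).

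All 12 libraries entered 1 edgeR 4.0.16 quasi-likelihood fit (limma 3.58.1, R 4.3.3) with a coefficient per group, TMM factors (0.9804 to 1.0182) and 6 residual degrees of freedom. Genes were kept by filterByExpr with a minimum count of 10, which left 18019. Tests were two-sided with Benjamini-Hochberg adjustment over all tested genes of a comparison, and a gene was called at an adjusted p under 0.05. The standard error of a log2 fold change was computed from the fold change and the F statistic, and is not given where F was near 0. The common biological coefficient of variation was 7.9523%. CPM values are edgeR's counts scaled to the TMM-adjusted library size, and a prior count of 2 was used for log CPM. Comparisons were each rescue with its EV control, the rescues with each other, dKO EV with ITGB4-lo EV, the difference of the dNp63 effects between the sublines, and the departure of the dual effect from the sum of the effects of dNp63 and TAp73. For a gene with 0 counts in a group the fold is a lower bound against a floor of 3 counts over the group, and with 1 to 3 counts it is a ratio with an exact 95% counting interval. In the interactions a gene with 3 counts or fewer in a group has no size given, only its adjusted p.

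Gene lists were fixed before the data were examined, as were the tests, the main alternatives and the rule for named genes. Of 605 list entries 603 matched a gene (CCDC39 and DDX58 did not), 585 different genes in 29 lists. They cover basal epithelial, hemidesmosome and epithelial basement membrane, desmosome and junction, epithelial regulator, mesenchymal, luminal, myoepithelial, cornified envelope, wound keratinocyte, EGFR and ERBB ligand, p53 family target, multiciliogenesis, Notch, WNT, Hippo target, TGF-beta, proliferation, interferon, NF-kB and cytokine, antigen presentation, cholesterol synthesis, integrated stress response, glycolysis and hypoxia, and mammary stem cell genes. Others cover leukocyte, endothelial and fibroblast markers, mitochondrially encoded genes, and heat shock and dissociation stress genes. TP63 and TP73 were left out of every list. Lists with at least 3 tested genes were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists, so the endothelial list had no test. With an estimated correlation 3 list calls held in ITGB4-lo dNp63 against EV (basal, mesenchymal and EGFR ligands) and 0 in each of the 3 rescues of dKO cells. Lists were run on the other comparisons too.

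Named genes are TP63, TP73 and ITGB4 in every comparison, and the 10 largest and 10 smallest log2 fold changes of a rescue against EV (5 and 5 otherwise) among called genes with a symbol, a mean of at least 2 CPM in the higher group and, except in the interactions, no overlap of the groups' CPM. Up to 4 called members of each list with the largest change and 2 not called with the highest CPM were also named, and other members may be named where a list is described. A few genes that the rule names are not reported here.

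Overlaps of calls were set beside 20 simulations of unchanged groups against the same EV libraries and beside the overlap of independent lists. Steps other than list correlation were tested on simulated counts. With 50 genes changed at each of 1.5, 2, 4 and 8-fold, the test found 22, 35, 46 and 49 for dKO dNp63 against EV (8 false of 160 calls among 17565 genes) and 24, 32, 42 and 47 for TAp73 against EV (12 of 157, 17559 genes). It found 26, 33, 43 and 47 for dual against EV (10 of 159, 17612 genes) and 33, 37, 47 and 49 for ITGB4-lo dNp63 against EV (9 of 175, 17566 genes). It found 14, 25, 39 and 45 for the difference between sublines (7 of 130, 17551 genes) and 14, 28, 42 and 48 for the departure from the sum (10 of 142, 17589 genes). With independent genes, camera called 0 lists in 5 simulations without change and a list shifted 1.5-fold in 5 of 5.

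Alternatives were DESeq2 1.42.0 with its size factors, RLE factors, library size alone, no filter or a filter of 1 CPM in 2 libraries, the replicate number as a block, only the compared libraries, stricter thresholds, an estimated list correlation, and each library left out in turn. Chosen after seeing the data were the leaving out of the pancreatic acinar genes and the removal of each library's smooth trend with GC content and transcript length (lowess span 0.3 over 10779 genes with a mean log2 CPM of at least 2, removed as offsets), alone and with a dKO EV library left out. Also chosen then was a replicate block of its own in each subline, alone and with that trend removed. The labels number the replicates of every group 1 and 2 and name no shared day or batch. Deviations of same-numbered libraries from their group means correlated at 0.1247 to 0.1806 in the 6 pairs of dKO groups and at 0.1293 in the 1 pair of ITGB4-lo groups. They ran from -0.1416 to 0.1162 in the 8 pairs across sublines. As -0.1416 is as large, a shared batch is not established. Counts that a block moves by over 1.5 times are also given. GC content was known for 99.75% of tested genes. Coordinates and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.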

Results

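RNA was measured in SUM159, an established human mammary carcinoma line, as 2 sublines named for their level of integrin beta 4 (ITGB4), the laminin-binding subunit of hemidesmosomes. In the ITGB4-hi subline the genes of the transcription factors p63 and p73 had been knocked out together (dKO), and these cells stably carried an empty vector (EV), the N-terminally truncated p63 isoform dNp63, the full-length p73 isoform TAp73, or both factors (dual). ITGB4-lo cells carried EV or dNp63. Each of the 6 groups held 2 libraries, described as biological duplicates, with total gene counts of 24017687 to 36974577. The question named by the series title and design is which genes dNp63 and p73 control in these cells. Of the variance between libraries 37.06% lay on a component that separated the sublines and 27.93% on a component with the dNp63 and dual libraries at its positive end. The lowest correlation of log CPM between replicates was 0.99194, and libraries of different groups reached 0.99306. Below, a ± after a level in CPM, counts scaled to library size, is the SD (n = 2) and after a log2 fold change the SE of the edgeR model. Counting intervals of ratios are at 95% and cover counting error only. A gene is said not to pass in the fit without a replicate block; of 569 such results for named genes 86 passed with a block within each subline and 167 with the GC trend removed as well.

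The introduced genes followed the labels in all 12 libraries. TP63 (ENSG00000073282, GRCh38 chromosome 3, 189631416 to 189897279) was at 1130.5 and 1017.1 CPM in the dKO dNp63 libraries, 1027 and 812.66 CPM in the dual libraries and 1680.6 and 1666 CPM in the ITGB4-lo dNp63 libraries. Its levels were 13.365 and 19.863 CPM with dKO EV, 18.122 and 18.889 CPM with TAp73, and 9.7363 and 9.7668 CPM with ITGB4-lo EV. TP73 (ENSG00000078900, chromosome 1, 3652520 to 3736201) was at 3392.2 and 3321.7 CPM with TAp73 and at 2646.4 and 2282.2 CPM in the dual libraries. It stayed between 6.3372 and 9.1105 CPM in the other 8 libraries. Gene counts include vector transcripts and do not separate isoforms, so the low counts in dKO EV cells do not tell knocked-out from intact transcript. ITGB4 (ENSG00000132470, chromosome 17, 75721328 to 75757818) was at 18.447 and 21.343 CPM with dKO EV and at 277.62 and 384.75 CPM with dKO dNp63. In the dual libraries it was at 203.84 and 264.79 CPM, and with TAp73 at 27.996 and 32.32 CPM. In ITGB4-lo cells it was at 28.235 and 19.815 CPM with EV and at 146.59 and 140.73 CPM with dNp63.

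**Figure D1:**
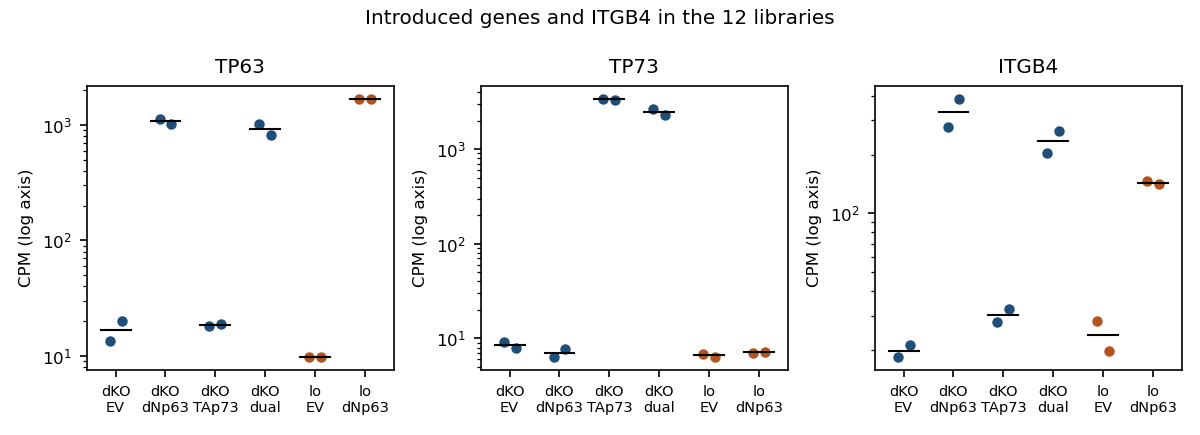
CPM on a log axis of TP63, TP73 and ITGB4 in each of the 12 libraries (dots) with the group means (lines), dKO groups in blue and ITGB4-lo groups in orange. ITGB4 lies between 140.73 and 384.75 CPM in the 6 libraries that carry dNp63 and between 18.447 and 32.32 CPM in the other 6.

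In dKO cells, dNp63 raised ITGB4 by a log2 fold change of 4.06 ± 0.19 and the EGFR ligand TGFA (ENSG00000163235, chromosome 2, 70447280 to 70554193) by 5.81 ± 0.17, from 1.07 ± 0.289 to 59.9 ± 2.09 CPM. TIMP3 (ENSG00000100234, chromosome 22, 32801701 to 32863043), a secreted inhibitor of metalloproteinases, fell from 372 ± 0.28 to 11.2 CPM, a log2 fold change of -5.05 ± 0.13. The retinaldehyde dehydrogenase ALDH1A1, a marker of some stem and progenitor cells, had 376 counts in both dNp63 libraries together and 2 in both EV libraries (ratio 171, counting interval 47.0 to 1416). Other large rises were those of DISP3 (ratio 177, 31.4 to 7035), the phospholipase PLCH2 (62.3, 16.9 to 519), the kinase STK26 (60.0, 16.3 to 501), the EGFR adaptor GAREM1 (log2 5.32 ± 0.18) and TMEM40 (5.21). Large falls included MXRA8 (ratio 114, 20.1 to 4563) and the formin DAAM2 (75.6, 25.5 to 369). They also included the phospholipase PLCB4 (log2 -5.12), the chemerin receptor CMKLR1 (-4.85), NKAIN2 (-4.61), myostatin (MSTN, -4.55), FAM180A (-4.54) and the guanine deaminase GDA (-4.40). The pancreatic enzymes PNLIP (ratio 41.8, 14.0 to 205) and CPA1 (39.7, 13.3 to 195) were also among the largest rises. A list of 27 pancreatic acinar genes, assembled after the values were seen, had 11 tested members and all 11 were higher with dNp63. Their summed level was 25.53 and 12.61 CPM in the dKO dNp63 libraries and 0.4089 to 2.751 CPM in the other 10.

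By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2577 of 18019 genes differed between dKO dNp63 and dKO EV at an adjusted p under 0.05, of which 1060 rose and 1517 fell, and 951 of them differed at least 2-fold. With the block within each subline and the GC trend removed 4705 were called. Adjusted p was 1.9e-09 for ITGB4, 8.3e-12 for TGFA, 3.7e-12 for TIMP3 and 6.4e-08 for ALDH1A1. Leaving out dNp63 replicate 1, dNp63 replicate 2 or EV replicate 2 lowered the count to 1584, 1602 and 1675, while the 21 genes named by the largest-change rule were called without each library in turn.

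Basal and adhesion genes were among those that rose with dNp63 (where no count adjusted over the list alone is given, it was the same). Of 14 tested basal epithelial genes 7 rose and 1 fell (7 and 1 adjusted over the list alone), with KRT14, a keratin of basal cells (ratio 90.9, 15.9 to 3625), and SERPINB5 (log2 2.18 ± 0.15) rising and IGFBP3 falling (-3.02 ± 0.63). EGFR (0.07 ± 0.10) did not pass. Of 13 hemidesmosome and basement membrane genes 6 rose and none fell (6 adjusted over the list alone), among them the hemidesmosome collagen COL17A1 (2.55 ± 0.41) and the integrin ITGA6 (0.92 ± 0.11). Camera, a competitive test of a list against all other genes, gave an adjusted p of 4.2e-07 for each of these lists at the preset correlation, and an adjusted p = 0.139 with an estimated correlation. Of 11 desmosome and junction genes 3 rose and 2 fell (3 and 3 adjusted over the list alone; camera adjusted p 0.288), with DSC2 (2.64 ± 0.47) and desmoplakin (DSP, 1.13 ± 0.11) higher and occludin (OCLN, -1.87 ± 0.22) and CXADR (-2.08 ± 0.40) lower. Among 8 epithelial regulators GRHL3 rose (ratio 21.8, 3.56 to 897) and CDS1 fell (camera adjusted p 0.974), the latter call ending without any of 8 libraries, and KLF4 (-0.19 ± 0.09; adjusted p 0.0136 with the block within each subline and the GC trend removed) and KLF5 (0.13 ± 0.10) did not pass.

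Members of the mesenchymal and myoepithelial lists fell more often than they rose. Of 24 mesenchymal genes 15 fell and 3 rose (16 and 3 adjusted over the list alone), with the collagens COL3A1 (-2.74 ± 0.26) and COL1A1 (-1.24 ± 0.14), the receptor PDGFRB (-2.34 ± 0.19) and fibrillin FBN1 (-1.73 ± 0.13) falling. Vimentin (VIM, -0.15 ± 0.08) did not pass (0.0370 with that block and the trend removed), and SNAI2, a transcription factor of epithelial-mesenchymal transition, rose from 35.8 to 66.2 CPM. The list's camera adjusted p was 8.5e-14, and 0.0626 with an estimated correlation. Of 12 myoepithelial and smooth muscle genes 7 fell and 1 rose (7 and 2 adjusted over the list alone; adjusted p 4.2e-07, and 0.136 with an estimated correlation), led by the myosin light chain MYL9 (-3.15 ± 0.22) and its kinase MYLK (-2.65 ± 0.16). Of 5 fibroblast markers, all of them also in the mesenchymal list, 3 fell and 1 rose (adjusted p 1.4e-05, and 0.0695 with an estimated correlation). Glycolysis and hypoxia genes fell in 8 of 22 cases and rose in 1 (10 and 1 adjusted over the list alone), with CA9 (-2.03 ± 0.27), NDRG1 (-1.02 ± 0.12) and the glucose transporter SLC2A1 (-0.81 ± 0.08) lower and LDHA (-0.04 ± 0.09) not passing. That list had an adjusted p of 4.4e-04, and 0.285 with an estimated correlation.

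Ligands and signalling lists moved in both directions. Of 9 EGFR and ERBB ligands TGFA, AREG (1.68 ± 0.24) and another member rose and NRG1 (-0.69 ± 0.12) and another fell (4 and 3 adjusted over the list alone). The list was called upward (adjusted p 5.6e-04, and 0.0695 with an estimated correlation) with a mean log2 fold change of 0.45 and a median of -0.28. With no filter on low counts its call ended (0.305). Hippo pathway targets fell in 10 of 21 cases and rose in 2 (13 and 3 adjusted over the list alone; adjusted p 0.00167, and 0.441 with an estimated correlation), among them CCN1 (-1.24 ± 0.18) and AXL (-0.74 ± 0.09). WNT pathway genes fell in 5 of 23 cases and rose in 1 (the same numbers adjusted over the list alone; adjusted p 0.00519, and 0.441 with an estimated correlation), including the ligands WNT7B (-4.28 ± 0.28) and WNT5A (-2.22 ± 0.20) and the antagonist DKK1 (-2.08 ± 0.30). NF-kB and cytokine genes rose in 7 of 20 cases and fell in 2 (11 and 2 adjusted over the list alone), with the chemokine CXCL2 at 1.71 ± 0.37. Their adjusted p was 0.00748, 0.527 with an estimated correlation and 0.0541 without EV replicate 1, which ends the call.

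The other lists were not called in dKO dNp63 against EV. Wound keratinocyte genes rose in 3 and fell in 5 of 12 cases (3 and 7 adjusted over the list alone; adjusted p 0.352), with interleukin IL1B (3.16 ± 0.33), IL1A (2.33 ± 0.23) and the integrin ITGA2 (1.49 ± 0.10) higher and the plasminogen activator PLAU (-3.31 ± 0.17) lower. TGF-beta pathway genes rose in 2 and fell in 6 of 19 cases (4 and 12 adjusted over the list alone; 0.119, and 0.0331 without EV replicate 1), with ID1 (1.21 ± 0.12) and TGFB2 (-2.13 ± 0.17) as examples. Of 37 p53 family targets 5 rose and 4 fell (8 and 4 adjusted over the list alone; 0.315), among them BTG2 (2.01 ± 0.19), FDXR (1.22 ± 0.16) and CDKN1C (-1.35 ± 0.22). Stem cell markers rose in 4 and fell in 2 of 11 cases (5 and 3 adjusted over the list alone; 0.0604), with a median of -0.46 and a mean of 0.63. The list was called when any of 5 libraries was left out (lowest adjusted p 0.0290, without dNp63 replicate 1) and with a filter of 1 CPM (0.0466). Cholesterol synthesis genes fell in 8 and rose in 1 of 23 cases (8 and 2 adjusted over the list alone; 0.0932). The TGF-beta and cholesterol lists were called downward with the GC trend removed (0.0274 and 0.0424) and with no filter on low counts (0.0216 and 0.0106). Notch genes rose in 4 and fell in 2 of 16 (4 and 3; 0.640), interferon genes fell in 4 of 25 (4; 0.314) and antigen presentation genes fell in 4 of 14 (4, with 1 rising; 0.222). Luminal genes rose in 1 and fell in 1 of 10 (1 and 2; 0.464), cornified envelope genes rose in 1 and fell in 2 of 6 (1 and 2; 0.648, tested upward against a median of -0.06 and a mean of -0.56). Multiciliogenesis genes rose in 1 of 13 (0.314) and stress response genes fell in 2 of 20 (0.314). Proliferation genes rose in 1 of 33 cases (0 adjusted over the list alone; 0.675), with MKI67 at 0.02 ± 0.08. Leukocyte genes fell in 1 of 5 cases (PTPRC, -3.37 ± 0.66; 0.821), mitochondrially encoded genes rose in 1 and fell in 1 of 13 (0.974), and of 15 heat shock genes 0 were called by edgeR (camera 0.887). Both tested endothelial genes passed, KDR (-2.87 ± 0.46) lower and EGFL7 (1.38 ± 0.34) higher, the latter losing its call without dNp63 replicate 1 or EV replicate 2 (highest adjusted p 0.117).

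TAp73 in dKO cells raised TGFA by 1.77 ± 0.20, from 1.07 to 3.65 CPM, and the basal keratin KRT17 by 1.76 ± 0.25, and lowered lipoprotein lipase (LPL) by a log2 fold change of -2.61 ± 0.19 and NHS by -2.96 ± 0.23. Their edgeR adjusted p was 6.3e-04, 0.0030, 6.2e-06 and 1.0e-05. The glucose and urate transporter SLC2A9 (1.56) and PITPNC1 (1.29) also rose, and DAAM2 (-3.10), the guanine nucleotide exchange factor TIAM1 (-2.45) and the membrane protein EMP2 (-2.44) fell. ITGB4 changed by 0.60 ± 0.18 and did not pass (adjusted p 0.141). It did with the block within each subline (0.00282) or no filter, settings that called far more genes. By the same edgeR test 107 genes differed from EV, 52 higher and 55 lower, with 70 of them at least 2-fold, and 2894 genes had an unadjusted p under 0.05. The count was 1797 without EV replicate 1 (312 higher and 1485 lower), 40 without EV replicate 2, 32 without TAp73 replicate 1 and 55 without TAp73 replicate 2. The GC content of genes went with the fold changes in this comparison (Spearman rho 0.633 across genes, which are not independent), with a median GC of 55.98% among the genes called higher and 47.81% among those called lower. In CPM relative to the mean of the libraries the rho was -0.53 for EV replicate 2, 0.194 for EV replicate 1, 0.412 for TAp73 replicate 1 and 0.312 for replicate 2. With each library's trend removed 104 genes were called, 89 of them among the 107. DESeq2 called 267 genes (30.71% higher), and with no filter 976 were called (25.82% higher). With the replicate number as a block the count was 363 (23.42% higher), and with a separate block in each subline, chosen after seeing the data, it was 1151 (22.68% higher) and 988 with the trend removed too (41.5% higher).

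Of the 20 genes named by rule in that comparison 10 lost their call when 1 library was left out. FUCA1 (2.19), OASL (1.96 ± 0.29), IFIT2 (1.75), RN7SL2 (1.91) and KIAA1549L (1.57) were among the rises, with adjusted p without EV replicate 2 of 0.145, 0.0571, 0.235, 0.449 and 0.0573. CNTN6 (-2.77), PLCB4 (-2.37) and CTNNA3 (-1.80) were among the falls, with 0.0584, 0.111 and 0.599, and MSTN (-1.74) had 0.0535 without TAp73 replicate 1. RN7SL2 is a copy of the abundant 7SL RNA, whose reads cannot be placed on a single copy with certainty.

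Few members of the lists passed with TAp73. Of 14 basal genes 3 rose (5 adjusted over the list alone), KRT17, SERPINB5 (0.79 ± 0.15) and the cell cycle regulator SFN (0.65 ± 0.11), and the list was called upward (adjusted p 2.6e-05, and 0.257 with an estimated correlation). Of 20 NF-kB and cytokine genes 2 rose, the adhesion receptor ICAM1 (1.13 ± 0.11) and the chemokine CCL5 (ratio 16.4, 4.26 to 140), and 10 rose adjusted over the list alone (adjusted p 8.0e-11, and 0.257 with an estimated correlation). Of 37 p53 family targets 3 rose (4 adjusted over the list alone), among them the cyclin-dependent kinase inhibitor CDKN1A (0.56 ± 0.09) and the mitochondrial reductase FDXR (0.96 ± 0.17). Of 25 interferon genes 2 rose (5 and 1 falling adjusted over the list alone). No hemidesmosome, wound or Notch gene was called by edgeR over all genes (5 rising and 1 falling, 1 rising and 1 rising adjusted over the list alone). Camera gave adjusted p of 0.0342 for p53 targets, 0.0458 for interferon, 0.00940 for hemidesmosome, 0.0342 for wound and 0.0444 for Notch genes, all upward, and 0.257, 0.257, 0.485, 0.649 and 0.430 with an estimated correlation. Without EV replicate 1 these calls ended (0.287, 0.287, 0.0886, 0.104 and 0.164), and without TAp73 replicate 2 as well (0.0522, 0.143, 0.0522, 0.143 and 0.195). The number of lists called was 7, and 2 without EV replicate 1, 11 without EV replicate 2 and 3 without TAp73 replicate 2. With the GC trend removed interferon (0.111) and Notch (0.379) were no longer called, and the other 5 lists were (basal 2.3e-05, NF-kB 9.1e-11, wound 0.0161, p53 targets 0.0262 and hemidesmosome 0.0459). The replicate block ended the interferon call (0.0667), and the block within each subline that call and Notch (0.0957 and 0.0507). A filter of 1 CPM in 2 libraries ended the p53 target, interferon and Notch calls (0.0663 for each) and the wound call (0.0553). The interferon call also ended with RLE factors (0.0516) or library size alone (0.0503). The calls of SERPINB5, SFN, CCL5, CDKN1A and FDXR each ended without EV replicate 2 (0.160, 0.146, 0.155, 0.0963 and 0.185).

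The remaining lists were not called with TAp73. Desmosome genes rose in 1 (CLDN1, 0.78 ± 0.16) and fell in 1 (DSP, -0.69 ± 0.11) of 11 cases (adjusted p 0.543), and both calls ended without TAp73 replicate 1 (0.160 and 0.183) or replicate 2. Of 24 mesenchymal genes 0 passed by edgeR (3 fell adjusted over the list alone; 0.773), with PDGFRB at -0.66 ± 0.17 (0.00282 with the block within each subline, 0.0176 by DESeq2 and 4.8e-05 with no filter) and COL1A1 at 0.02 ± 0.13. The smooth muscle actin ACTA2 (1.05 ± 0.21) was the only one of 12 myoepithelial genes to rise (0.809), and NGFR (1.71 ± 0.35) the only one of 11 stem cell markers (0.0568). ID3 (0.49 ± 0.10) rose among 19 TGF-beta genes (2 rose and 3 fell adjusted over the list alone; 0.773), and the kinesin CENPE (-1.09 ± 0.21) and TOP2A (-0.38 ± 0.08) fell among 33 proliferation genes (3 adjusted over the list alone; 0.414). The calls of ACTA2, NGFR, ID3, CENPE and TOP2A each ended without EV replicate 2 (0.166, 0.483, 0.212, 0.449 and 0.400), and with the GC trend removed (0.0694, 0.0610, 0.0847, 0.113 and 0.523). TGFA was the 1 EGFR ligand of 9 to rise (0.137). No gene passed over all genes in the epithelial regulator (0.414), luminal (0.383), cornified envelope (0.80), multiciliogenesis (0.414), WNT (0.108), Hippo (0.367), antigen presentation (0.31), cholesterol (0.819), stress response (0.539), glycolysis (0.414), leukocyte (0.137), fibroblast (0.773), mitochondrial (0.63) and heat shock (0.414) lists. Adjusted over the list alone, 3 glycolysis genes rose and 1 fell, 2 each of the multiciliogenesis, cholesterol and stress response genes fell, and 1 each of the epithelial regulators, WNT and fibroblast genes fell. Without EV replicate 2 the ligand (0.0429), Hippo (0.0494), leukocyte (0.0192) and stem cell (0.00951) lists were called upward. The leukocyte list was also called without TAp73 replicate 1 (0.0121), and the WNT list downward without TAp73 replicate 2 (0.0393). The stem cell list was also called without TAp73 replicate 1 (0.0393), dual replicate 1 or 2 (0.0470 for both) and ITGB4-lo dNp63 replicate 1 (0.0430) or 2 (0.0428). With the GC trend removed the WNT list was called downward (0.00540) and the ligand (0.0376) and stem cell (0.0463) lists upward, the last also with no filter (0.0124).

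With both factors, ALDH1A1 (ratio 157, 43.0 to 1299), TGFA (5.26 ± 0.17, 40.9 ± 1.8 CPM), GAREM1 (5.15), TMEM40 (4.51), SLC2A9 (3.89), the metalloproteinase ADAM28 (3.62), the sulfatase SULF1 (3.48) and ITGB4 (3.56 ± 0.19) rose in dKO cells. DAAM2 (ratio 217, 38.5 to 8613), MXRA8 (110, 19.2 to 4369), PLCB4 (68.8, 23.2 to 337), WNT7B (log2 -5.75), LPL (-5.59), TIMP3 (-5.59), CMKLR1 (-5.56), EMP2 (-5.31) and CNTN6 (-5.03) fell. The edgeR test called 2838 genes against EV, 1138 higher and 1700 lower (5009 with the block within each subline and the GC trend removed), with 903 of them at least 2-fold. The count was 1492 without dual replicate 1, 1701 without dual replicate 2 and 1740 without EV replicate 2, and the 20 genes named by the largest-change rule were called without each library in turn.

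Mesenchymal genes fell in 15 of 24 cases with both factors and rose in 2 (17 and 2 adjusted over the list alone), with PDGFRB (-2.14 ± 0.18) and COL3A1 (-1.79 ± 0.24) as examples (camera adjusted p 2.1e-10, and 0.106 with an estimated correlation). Myoepithelial genes fell in 7 of 12 and rose in 1 (8 and 1 adjusted over the list alone; 9.8e-06, and 0.233 with an estimated correlation), including MYL9 (-2.56 ± 0.21), and 3 of 5 fibroblast genes fell (8.0e-04, and adjusted p = 0.164 with an estimated correlation). Glycolysis genes fell in 8 of 22 (15 fell and 2 rose adjusted over the list alone; 1.6e-05, and 0.279 with an estimated correlation), with CA9 at -3.35 ± 0.33. Hippo targets fell in 11 of 21 (8.0e-04, and adjusted p = 0.411 with an estimated correlation) and stress response genes in 4 of 20 (0.0169, and 0.435 with an estimated correlation), among them the folate enzyme ALDH1L2 (-1.26 ± 0.20). The stress response call ended without EV replicate 1 (0.0941). Basal genes rose in 6 and fell in 2 of 14 (adjusted p 0.0169, and 0.411 with an estimated correlation). KRT14 (ratio 37.02, 6.26 to 1499) was higher and IGFBP3 (10.9, 3.40 to 55.7) lower, and KRT17 fell (-1.87 ± 0.39), a call that ended without dual replicate 1 (0.0553) or EV replicate 2 (0.0564). The basal list lost its call without dual replicate 2 (0.0986) or EV replicate 1 (0.0603). With no filter on low counts the basal and fibroblast calls ended (0.0539 for both). Hemidesmosome genes rose in 6 and fell in 2 of 13 (7 and 2 adjusted over the list alone; 0.00578, and adjusted p = 0.411 with an estimated correlation), with the laminin chain LAMB3 lower (-1.04 ± 0.17). Wound genes rose in 3 and fell in 5 of 12 (3 and 6 adjusted over the list alone; 0.0292, and adjusted p = 0.435 with an estimated correlation), a call that ended without dual replicate 1 (0.151), EV replicate 1 (0.147), TAp73 replicate 1 (0.0522), dKO dNp63 replicate 2 (0.0501) or ITGB4-lo dNp63 replicate 2 (0.0545). It also ended with no filter (0.108), a filter of 1 CPM (0.0552), the replicate block (0.0501) or the block within each subline (0.0525).

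The remaining lists were not called with both factors. The adjusted p was 0.639 for desmosome genes (3 rose and 3 fell of 11), 0.227 for epithelial regulators (3 fell of 8, ESRP1 by -1.46 ± 0.27), 0.423 for luminal genes (2 fell of 10) and 0.861 for cornified envelope genes (2 rose and 2 fell of 6). It was 0.154 for EGFR ligands (2 rose and 2 fell of 9), 0.444 for p53 targets (5 rose and 5 fell of 37), 0.421 for multiciliogenesis genes (2 rose and 1 fell of 13), 0.163 for Notch (4 rose and 2 fell of 16) and 0.0919 for WNT genes (2 rose and 6 fell of 23; 0.0213 without dual replicate 2). It was 0.126 for TGF-beta genes (2 rose and 9 fell of 19), 0.671 for proliferation (0 of 33 by edgeR), 0.114 for interferon (6 fell of 25), 0.146 for NF-kB (4 rose and 1 fell of 20) and 0.126 for antigen presentation genes (4 fell of 14). Cholesterol genes (1 rose and 8 fell of 23) had 0.126, stem cell markers (4 rose and 2 fell of 11) 0.146, leukocyte genes (1 fell of 5) 0.421, mitochondrial genes (1 rose and 1 fell of 13) 0.671 and heat shock genes (0 of 15 by edgeR) 0.671. With the GC trend removed the TGF-beta (0.0352), WNT (0.0393) and antigen presentation (0.0393) lists were called downward. With no filter the TGF-beta (0.0320), interferon (0.0175) and cholesterol (0.0327) lists were, and with the block within each subline the NF-kB list was called upward (0.0193). Adjusted over the list alone, EGFR ligands had 3 rising and 6 falling, p53 targets 7 and 6, Notch genes 8 and 4, TGF-beta genes 4 and 12 and NF-kB genes 7 and 3. It gave 1 rising and 9 falling for cholesterol, 5 falling for antigen presentation, 4 rising and 3 falling for desmosome and 1 rising and 2 falling for luminal genes.

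**Figure D2:**
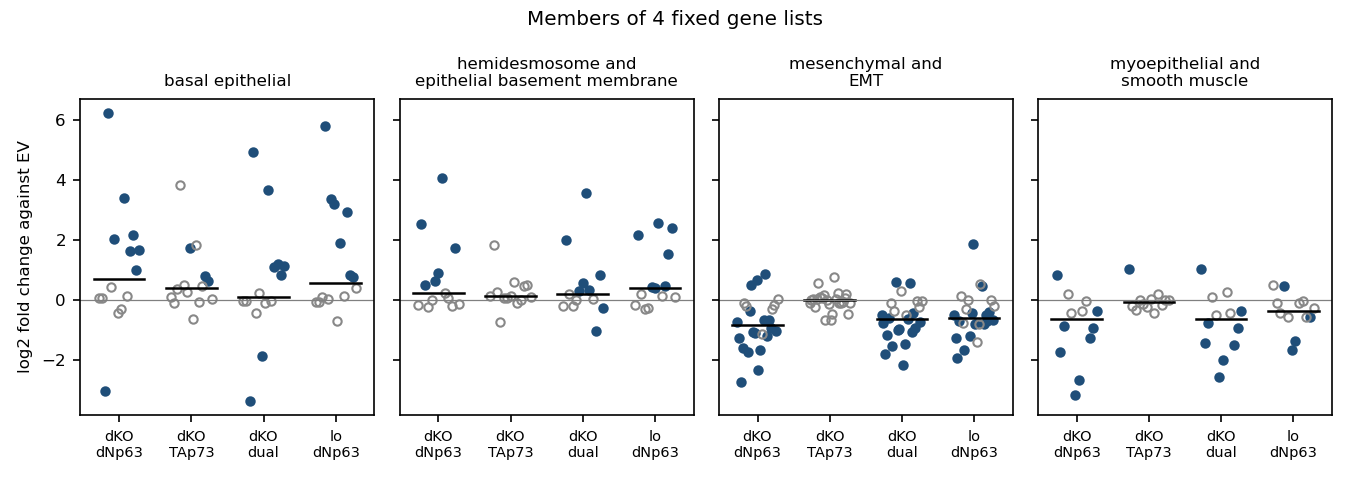
The log2 fold change against EV of each member of 4 fixed lists in the 4 comparisons with EV, with filled points for genes at an adjusted p under 0.05, open points for the others and a line at the median. Of 24 mesenchymal genes 15 fell with dNp63 and 15 with both factors in dKO cells, 13 with dNp63 in ITGB4-lo cells and 0 with TAp73.

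Compared directly with dNp63 cells, TAp73 cells had higher LRRC7 (4.43), the prostaglandin synthase PTGES (4.05), GDA (3.83) and SCG5 (3.82) and lower ADAM28 (-5.67), DISP3 (-5.67), CPB1 (-5.30) and STK26 (-5.10). The edgeR test called 2163 genes, 1252 higher and 911 lower (3367 with the block within each subline, 4393 with the GC trend removed too). Without dNp63 replicate 1 or 2 that count was 1356 and 1152, and without TAp73 replicate 1 or 2 it was 1223 and 1242. Against TAp73, dual cells had higher ADAM28 (4.99), ALDH1A1 (4.97), GAREM1 (4.02) and TGFA (3.49) and lower WNT7B (-5.06), CMKLR1 (-4.23), TIMP3 (-4.21), the melanoma antigen MAGEC2 (-3.99) and osteopontin (SPP1, -3.83; adjusted p 0.0532 without dual replicate 1). The test called 2415 genes, 1001 higher and 1414 lower (3829 and 5032). Without dual replicate 1 or 2 that count was 1133 and 1277, and without TAp73 replicate 1 or 2 it was 1267 and 1310. Dual against dNp63 cells gave 48 calls, 13 higher and 35 lower (151 and 304, and 174 with no filter), and 992 genes had an unadjusted p under 0.05. FARP1, a guanine nucleotide exchange factor, fell from 8.14 to 1.86 CPM (log2 -2.13 ± 0.17, edgeR adjusted p 2.5e-05), and DISP3 fell (-2.45). The collagen-processing genes ADAMTS2 (1.88) and PCOLCE (1.09), the lipid transporter ABCA3 (1.30) and AOC1 (1.28) rose, with highest adjusted p of 0.298, 0.105, 0.0595 and 0.329, each without dNp63 replicate 1. The acinar genes CPB1 (at least 60.6-fold lower, on a floor of 3 counts over the group), PNLIP (ratio 132, 23.3 to 5256) and CPA1 (125, 22.1 to 4991) were lower in the dual cells. DESeq2 did not call CPA1 (0.130), and its call ended without dNp63 replicate 1 (0.0595), dual replicate 1 (0.0991) or dual replicate 2 (0.134). The PNLIP call ended without dual replicate 1 (0.0639) or 2 (0.0502). Without the acinar list 38 genes were called. Without dNp63 replicate 1 or 2 the count was 19 and 17, and without dual replicate 1 or 2 it was 9 and 12.

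Where both factors were present, 64 genes departed from the sum of the effects of dNp63 and TAp73 on the log2 scale, 18 above and 46 below it (111 genes with the replicate block, 40.54% of them above, and 457 with the block within each subline, 56.46% above, against 28.12% without a block; 697 with the GC trend removed too), and 1925 genes had an unadjusted p under 0.05 by edgeR. DESeq2 called 115, the fit of only the compared libraries 111 and that with no filter 541 (59.33% above). TGFA lay below the sum by -2.32 ± 0.23 (adjusted p 5.4e-04), FARP1 by -2.47 ± 0.27 (9.0e-04), SERPINB5 by -1.76 ± 0.21 and ICAM1 by -1.30 ± 0.16. TMEM40 (-4.63), KRT17 (-3.20) and the annexin ANXA8 (-2.71), which has a near-identical copy, also lay below, and MSTN (2.88), NHS (1.97), LRRTM3 (1.81) and the calcium channel CACNA1C (1.78) above. PLCH2 was called below the sum too (adjusted p 0.00683), but has 2 counts with EV, so its fitted size is not given. ITGB4 was at -1.10 ± 0.24 and did not pass (adjusted p 0.0861). It did with the block within each subline (2.7e-04), no filter or only the compared libraries (0.0458), settings that called more genes. Without EV replicate 1 the count was 593 and without ITGB4-lo EV replicate 2 it was 99. It was 40 and 35 without dNp63 replicate 1 or 2, 22 and 33 without dual replicate 1 or 2, and 26 and 33 without TAp73 replicate 1 or 2. The calls of ANXA8 (0.0949 without EV replicate 2), KRT17 (0.0546 without dNp63 replicate 2), MSTN (0.244 without dual replicate 2) and NHS (0.0720 without TAp73 replicate 1) ended without at least 1 library. The fold change also went with GC content (rho -0.481 across genes).

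The basal list lay below the sum, with 5 of 14 genes called (camera adjusted p 9.8e-13, and 0.0934 with an estimated correlation). So did the NF-kB list (1 of 20, 5 adjusted over the list alone; 2.9e-12, and 0.149 with an estimated correlation), the hemidesmosome list (2 of 13, 7 below and 1 above adjusted over the list alone; 1.9e-09, and 0.111 with an estimated correlation) and the wound list (2 of 12, 3 adjusted over the list alone; 6.1e-05, and 0.232 with an estimated correlation). Among 9 EGFR ligands only TGFA passed (4 adjusted over the list alone), and that list's call held with an estimated correlation (6.8e-07, and adjusted p = 0.0407 with an estimated correlation). The p53 target (2 of 37, 3 adjusted over the list alone; 0.0169), interferon (1 of 25, 5; 0.0113), stem cell (0.0169), leukocyte (0.0169), stress response (0.0164), glycolysis (0.0422) and proliferation (0.0434) lists were called below the sum and the WNT list (0.0120) above it, with adjusted p of 0.111, 0.111, 0.135, 0.377, 0.436, 0.439, 0.436 and 0.436 with an estimated correlation. The 1 called stress response gene, ALDH1L2, lay above the sum (1.56 ± 0.30), and the other 5 of these lists had 0 genes called by edgeR (3 stem cell and 1 glycolysis gene below adjusted over the list alone).

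**Figure D3:**
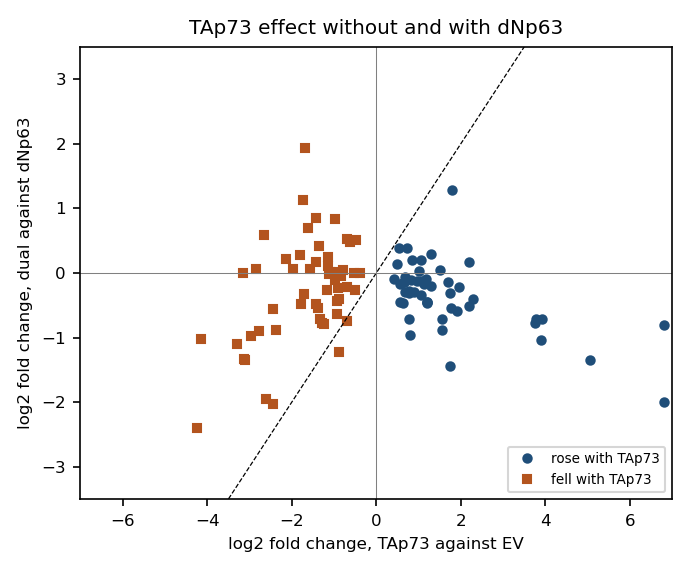
For the 51 genes that rose (circles) and the 55 that fell (squares) with TAp73 in dKO cells, TP73 left out, the log2 fold change of TAp73 against EV (x) and of dual against dNp63 (y), with a dashed line at equal effects. The median of the 51 genes is 1.19 on the x axis and -0.286 on the y axis, and that of the 55 genes -1.37 and -0.213.

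In ITGB4-lo cells dNp63 raised TGFA from 1.69 ± 0.403 to 37.3 ± 2.44 CPM (4.44 ± 0.15, edgeR adjusted p 1.4e-10) and ITGB4 by 2.57 ± 0.18 (6.5e-07). DISP3 (ratio 114, 38.8 to 557), the lipid receptor TREM2 (68.6, 18.7 to 572), KRT14 (61.3, 20.7 to 300), apolipoprotein D (APOD, log2 5.13), TMEM40 (3.52), LRP4 (3.03), the calcium-binding protein S100A2 (2.94) and PLCH2 (2.88) rose. Myostatin (MSTN, -4.41), the chemokine CXCL12 (-3.01), the hyaluronan-degrading CEMIP (-2.90), CYP4B1 (-2.83), cadherin CDH6 (-2.65), the transcription factor TOX (-2.25), STAC2 (-2.13), SCG5 (-2.12), SVEP1 (-2.12) and PARM1 (-2.04) fell. The edgeR test called 957 genes, 416 higher and 541 lower (1763 with the block within each subline, 2839 with the GC trend removed too), with 293 at least 2-fold, and the 21 genes named by the largest-change rule were called without each library in turn. The count was 555 without dNp63 replicate 1 and 375 without dNp63 replicate 2 of this subline.

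Of 14 basal genes 7 rose and none fell in ITGB4-lo cells, with KRT16 (3.37 ± 0.53), KRT17 (3.21 ± 0.53) and SFN (0.77 ± 0.11) beside KRT14 (camera adjusted p 1.7e-15, and 0.0406 with an estimated correlation). Keratins 14, 16 and 17 share long stretches of sequence, so reads can be split between them. Of 13 hemidesmosome genes 7 rose (8 rose and 1 fell adjusted over the list alone; 5.7e-13, and adjusted p = 0.0588 with an estimated correlation), with COL17A1 (2.16 ± 0.30) and LAMB3 (1.53 ± 0.16). Mesenchymal genes fell in 13 of 24 and rose in 2 (16 and 3 adjusted over the list alone; 1.8e-12, and adjusted p = 0.0406 with an estimated correlation), with COL3A1 (-1.92 ± 0.33) and FBN1 (-1.67 ± 0.12) lower and PDGFRA higher (1.87 ± 0.20). EGFR ligands rose in 3 and fell in 2 of 9 (2.0e-05, and adjusted p = 0.0406 with an estimated correlation), with AREG at 1.60 ± 0.22 and NRG1 at -1.23 ± 0.12, a mean of 0.35 and a median of -0.29. With no filter on low counts that call ended (0.287). NF-kB genes rose in 9 of 20 (10 rose and 1 fell adjusted over the list alone; 1.7e-09, and adjusted p = 0.237 with an estimated correlation). Among them were CSF3 (ratio 11.9, 3.78 to 60.1) and CXCL8 (1.79 ± 0.40), whose calls ended without dNp63 replicate 2 (0.189 and 0.241).

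Further lists were called in ITGB4-lo cells at the preset correlation and lost the call with an estimated correlation. Hippo targets fell in 5 of 21 (9 fell and 2 rose adjusted over the list alone; 1.1e-04, and adjusted p = 0.263 with an estimated correlation), with CCN2 at -1.26 ± 0.18. Myoepithelial genes fell in 3 and rose in 1 of 12 (5 and 2 adjusted over the list alone; 0.00122, and adjusted p = 0.263 with an estimated correlation), with MYL9 at -1.66 ± 0.21. Wound genes rose in 3 and fell in 1 of 12 (4 and 2 adjusted over the list alone; 0.00475, and adjusted p = 0.2995 with an estimated correlation), with IL1B at 2.30 ± 0.30. WNT genes fell in 4 of 23 (5 fell and 1 rose adjusted over the list alone; 0.0117, and adjusted p = 0.384 with an estimated correlation). Fibroblast genes fell in 3 and rose in 1 of 5 (4 and 1 adjusted over the list alone; 0.00621, and adjusted p = 0.122 with an estimated correlation). Heat shock genes rose in 3 and fell in 1 of 15 (5 and 1 adjusted over the list alone; 0.00781, and adjusted p = 0.386 with an estimated correlation). Mitochondrially encoded genes had 0 of 13 called by edgeR and an upward list call (0.00621, and adjusted p = 0.411 with an estimated correlation). Notch genes rose in 2 of 16 (2 rose and 1 fell adjusted over the list alone; 0.0142, and adjusted p = 0.263 with an estimated correlation). Interferon genes fell in 4 of 25, with IFIT3 at -1.27 ± 0.22 (0.0250, and adjusted p = 0.204 with an estimated correlation). Luminal genes fell in 2 of 10 (0.0318, and adjusted p = 0.294 with an estimated correlation). Antigen presentation genes rose in 2 of 14, with HLA-E at 0.41 ± 0.07 (0.0338, and adjusted p = 0.263 with an estimated correlation). Proliferation genes fell in 1 of 33 (0.0460, and adjusted p = 0.384 with an estimated correlation). Without ITGB4-lo EV replicate 1 the wound (0.142), WNT (0.155), fibroblast (0.123) and heat shock (0.668) calls ended. Without EV replicate 2 of that subline the luminal (0.200), interferon (0.144), mitochondrial (0.0568) and proliferation (0.279) calls ended. Without its dNp63 replicate 1 the Notch (0.0956), interferon (0.153) and luminal (0.0713) calls ended, and without replicate 2 the heat shock (0.2995), mitochondrial (0.156) and proliferation (0.140) calls. The antigen presentation call ended without any of 11 libraries (highest adjusted p 0.269). With no filter the luminal (0.136), antigen presentation (0.117), fibroblast (0.0649) and proliferation (0.0526) calls ended, and with a filter of 1 CPM the interferon (0.0597) and proliferation (0.0742) calls.

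Lists not called in ITGB4-lo cells were desmosome (1 rose and 2 fell of 11; adjusted p 0.579), epithelial regulators (0 of 8 by edgeR; 0.694) and cornified envelope genes (1 rose of 6; 0.386). Others were p53 targets (4 rose and 3 fell of 37; 0.206), multiciliogenesis (1 rose of 13; 0.199), TGF-beta (1 rose and 2 fell of 19; 0.386) and cholesterol genes (0 of 23 by edgeR; 0.621). The rest were stress response (0 of 20 by edgeR; 0.206, and 0.00223 without EV replicate 1 of that subline), glycolysis (1 fell of 22, 1 rose and 1 fell adjusted over the list alone; 0.386, and 0.0263 without that library), stem cell markers (3 rose and 1 fell of 11, 3 and 2 adjusted over the list alone; 0.297) and leukocyte genes (0 of 5 by edgeR; 0.240). Of the 2 endothelial genes KDR fell (-1.43 ± 0.27), a call that ended without EV replicate 1 (0.0627) or dNp63 replicate 2 (0.0867).

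The effects of dNp63 in ITGB4-lo and dKO cells were compared directly as an interaction, given as the ITGB4-lo effect minus the dKO effect. TIMP3, which fell from 372 to 11.2 CPM in dKO cells, was at 6.13 ± 0.97 CPM with EV and 5.44 ± 1.25 CPM with dNp63 in ITGB4-lo cells (interaction 4.87 ± 0.19, edgeR adjusted p 1.7e-09). ALDH1A1 rose to 6.71 ± 0.29 CPM in dKO cells and was at 0.594 and 0.505 CPM in ITGB4-lo cells (adjusted p of the interaction 3.6e-05). Its 2 counts with dKO EV leave the size of that difference unmeasured. The ITGB4 effect was smaller in ITGB4-lo cells (-1.48 ± 0.25, 2.7e-03) and the TP63 difference larger (1.40 ± 0.20, 1.0e-03). Desmoplakin (DSP) rose in dKO cells and fell in ITGB4-lo cells (-1.64 ± 0.15), although its fall lost its call without ITGB4-lo dNp63 replicate 2 (0.0816), dNp63 replicate 1 (0.0751) or EV replicate 1 (0.0518). KRT17 (3.64 ± 0.63), LAMB3 (1.72 ± 0.23), S100A2 (1.30 ± 0.18), PLAU (2.00 ± 0.30) and GDA (4.39) had higher and SERPINB5 (-1.32 ± 0.19) a lower effect in ITGB4-lo cells. In all 507 genes differed, 312 higher and 195 lower (943 with the block within each subline, 1676 with the GC trend removed too and 838 with no filter), and 325 without ITGB4-lo dNp63 replicate 2. TMEM63C was also called lower (0.00121, 1 count with dKO EV). Calls of MAGEC2 (higher, 0 counts with ITGB4-lo EV), MYBPC1 (4.22), PNLIP (lower, 3 counts with dKO EV), CPB1 (-5.97) and TESC (lower, 1 count with dKO EV) ended without at least 1 library (highest adjusted p 0.129, 0.0512, 0.0625, 0.109 and 0.238, without ITGB4-lo dNp63 replicate 2, dNp63 replicate 2, EV replicate 1, EV replicate 1 and dKO dNp63 replicate 1). The mesenchymal (5 of 24 called upward, 6 and 1 downward adjusted over the list alone; camera adjusted p 0.00452), myoepithelial (2 of 12; 0.00189), glycolysis (3 of 22, 5 adjusted over the list alone; 6.6e-04) and antigen presentation (2 of 14, 5 adjusted over the list alone; 0.00122) lists were called upward, each with an adjusted p = 0.334 with an estimated correlation. The basal (0.957) and hemidesmosome (0.682) lists were not called. The wound (3 of 12, 5 up and 1 down over the list alone; 0.00452), cholesterol (2 of 23; 0.0105), fibroblast (2 of 5; 0.0105) and mitochondrial (0 of 13; 0.0399) lists were called upward and the proliferation list downward (0 of 33; 0.0423). These calls ended with an estimated correlation (adjusted p 0.485, 0.334, 0.334, 0.754 and 0.586).

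Of the genes called in both sublines, 611 changed in the same direction, 278 up and 333 down, against 24.5 and 45.6 by chance for independent lists, and 19 in opposite directions. Across genes the effects had a Pearson r of 0.480 and a Spearman rho of 0.380, with no library shared. Among the 610 of these genes other than TP63, 452 had a smaller effect in ITGB4-lo cells, with a median ratio of 0.757. Of the 630 shared calls (1043 with the block within each subline, 1581 with the GC trend removed too) 398 and 301 were left without ITGB4-lo dNp63 replicate 1 or 2.

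**Figure D4:**
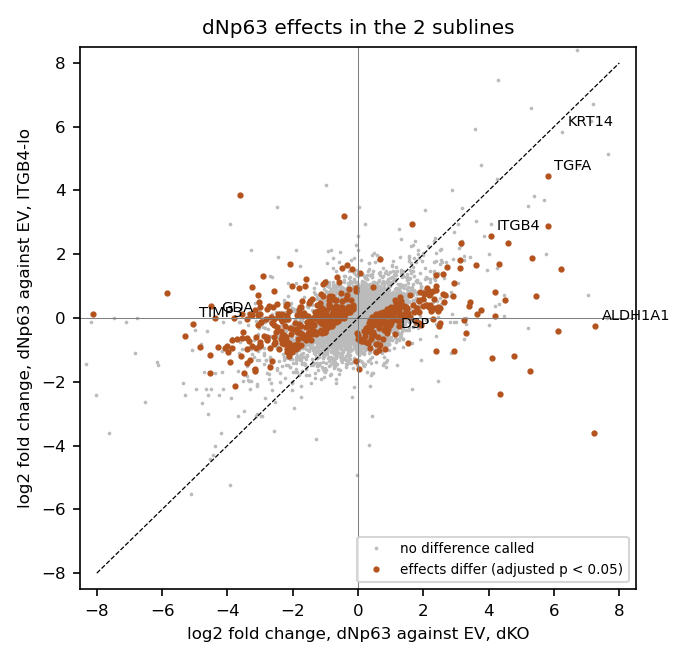
The log2 fold change of dNp63 against EV in dKO (x) and ITGB4-lo cells (y) for each tested gene, with the 507 genes whose effects differ in orange. TIMP3 lies at -5.05 on the x axis and ITGB4 at 4.06.

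The effects in dKO cells share the EV libraries, and the 2 of them cannot be split into sets of 2 libraries, so part of any excess over chance may come from them. dNp63 and TAp73 shared 87 calls, 39 up, 45 down and 3 opposite, against 3.06 up and 4.63 down for independent lists. In 20 simulations of unchanged groups the mean was 0.05, which sets no scale for the 87, since those groups had means of only 0.35 and 0.3 calls. Their r was 0.486 (0.537 in the simulations) and their covariance 0.148 (0.0584). The 87 became 191 with the replicate block, 555 with the block within each subline (565 with the GC trend removed too), 474 with no filter, 1109 without EV replicate 1, 33 without EV replicate 2, and 25 and 42 without TAp73 replicate 1 or 2. dNp63 and dual shared 2049 calls, 785 up, 1263 down and 1 opposite (66.9 and 143 for independent lists), with r 0.840 (0.517) and covariance 0.425 (0.0581). TAp73 and dual shared 89 calls, 39 up, 46 down and 4 opposite (3.28 and 5.19), with r 0.485 (0.526) and covariance 0.146 (0.0581).

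The starting lines differed widely. dKO EV cells had higher MAGEC2 (at least 86.1-fold), BEX1 (log2 7.62), contactin CNTN6 (ratio 165, 29.02 to 6550), the AMP-activated kinase subunit PRKAA2 (162, 28.6 to 6450) and LPL (140, 47.4 to 681) than ITGB4-lo EV cells. They had lower TESC (160, 28.3 to 6333), the potassium channel KCNH5 (134, 36.7 to 1107), HOXD13 (72.9, 24.7 to 356), the dopamine receptor DRD2 (69.5, 19.0 to 579) and PHACTR1 (log2 -5.08). ITGB4 did not pass (-0.28, adjusted p 0.324; 0.0273 with no filter and 0.0436 with the block within each subline and the GC trend removed), and TP63 was higher by 0.76 (0.0029; 0.0522 without dKO EV replicate 2). The edgeR test called 3792 genes, 1879 higher and 1913 lower (49.55% higher), with 1110 at least 2-fold. With only the compared libraries in the fit it called 2147 (37.17% higher), and with the block within each subline and the GC trend removed 6429. Subline and knockout differ together in this comparison and cannot be separated.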

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

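The tests of GC content, of the cultures, of the departure from additivity other than its GC test, and of acinar gene levels in other libraries were chosen only after the result was seen; the test of equal acinar shares, the GC test of the additivity pattern and its test in held-out replicates were written before their results. The values below were picked out because effects under the same contrast differed by an interaction test in edgeR.

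The effect of dNp63 differed between ITGB4-lo and dKO cells for 507 genes, given here as the ITGB4-lo log2 effect minus the dKO effect. Larger values in ITGB4-lo cells were those of TIMP3 (4.87), GDA (4.39) and MYBPC1 (4.22), and a lower one that of CPB1 (-5.97). MAGEC2 was called higher (adjusted p 0.0208) and ALDH1A1 (3.6e-05), PNLIP (0.00234), TMEM63C (0.00121) and TESC (0.0421) lower, but each has a group with 3 counts or fewer, so a fitted size would depend on the prior count. Counts over both libraries were 0 for MAGEC2 with ITGB4-lo EV, and with dKO EV 2, 3, 1 and 1 for the others in that order. TP63 itself differed by 1.40 and ITGB4 by -1.48. Calls of MAGEC2, MYBPC1, PNLIP, CPB1 and TESC ended without at least 1 library.

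The effect of both factors differed from the sum of their effects for 64 genes. It lay above the sum for MSTN (2.88), NHS (1.97), LRRTM3 (1.81) and CACNA1C (1.78) and below it for TMEM40 (-4.63), KRT17 (-3.20), ANXA8 (-2.71) and FARP1 (-2.47). PLCH2 was called below it too (adjusted p 0.00683), with 2 counts in dKO EV and so no size. Calls of MSTN, NHS, KRT17 and ANXA8 ended without at least 1 library.

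Pancreatic acinar transcripts, behind PNLIP and CPB1 above, were present in both dKO dNp63 libraries, with 754 and 334 counts over 27 genes, such as CPB1 (142 and 48), CPA1 (93 and 38), PNLIP (91 and 47) and PRSS1 (63 and 36), some of which have near-identical copies. Activation by dNp63 is argued against by the dual and the ITGB4-lo dNp63 libraries, which carry TP63 at 919.85 and 1673.3 CPM (1073.8 CPM with dKO dNp63) and hold 2.87% and 6.09% of the summed acinar CPM of the dKO dNp63 libraries. Reads from pancreas tissue or another pancreas library stay open and need 1 ratio between the replicates over genes, which was seen: replicate 1 held 69.23% of the acinar counts, with gene shares from 54.29% to 90.91%, and a Monte Carlo test of equal shares over 21 genes gave p = 0.572 (permutation of counts, 100000 resamples). The reads make up 0.00258% of dKO dNp63 replicate 1, insulin had 1 count in both libraries together, and no sort or gate is named that would remove such cells. The list was written after the first of these genes were seen among the largest changes, and a candidate source outside these cells is a hypothesis.

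The number of TAp73 calls, 107, was 1797 without dKO EV replicate 1 and 40 without replicate 2, and the EV libraries differ in their trend with GC content (rho -0.53 for replicate 2 and 0.194 for replicate 1). With each library's trend removed, most calls without replicate 1 were lost, so they depended on it. In TAp73 libraries simulated with these trends, 46 false calls were made with both EV libraries. Without replicate 1 there were more, but far fewer than in the data. Removing what was put in left 21 and fewer. The trend may lie behind some of the 107. A difference between the EV cultures cannot be told apart from a remaining library difference, since each is 1 library. No biological explanation was tested, since the replicates share a group.

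Over the 51 genes that rose with TAp73 in dKO cells the median log2 fold change of dual against dNp63 was -0.286 (-0.445 to -0.139). With the GC trend removed it was -0.289, which argues against that trend between dual and dNp63 libraries. Its part in the picking of the 51 was not tested. Over the 55 that fell it was -0.213 (-0.478 to 0.00872), with 32 lower and 23 higher. Bootstrap intervals here are over genes and hold no spread between libraries. Chance values of the EV libraries would also leave no rise here. Genes picked without 1 replicate of EV and TAp73 rose in the held-out pair (1.07 and 1.19), above their dual against dNp63 medians (-0.32 and -0.455). As only 2 and 5 were picked, chance stays open for the 51. For the 12 of the 51 genes that were not called higher with dNp63 the median was -0.446 (-0.924 to -0.159), with 10 of 12 lower. A rise, which a ceiling reached with dNp63 or a lower TP63 level would leave to genes that dNp63 does not raise, was not seen. But these 12 genes were only not called, so a smaller rise with dNp63 is not excluded and both explanations stay open for them. For the 39 genes that both factors raised it was -0.208, with 30 of 39 lower, and a lower TP63 level in the dual libraries (log2 -0.22, adjusted p 1 by edgeR) stays open for them, as the 415 genes that dNp63 raised in ITGB4-lo cells also lay lower (-0.155). A lower TP73 level in dual than in TAp73 cells, called by edgeR but not without dual replicate 2, was not tested. It stays open here and for the 64 genes. The presence of both factors together, the biological difference that the design names, stays open for the 12 genes and was not tested further.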

How the results depend on the processing

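Among the alternatives below, the removal of the GC and length trend, that of the acinar genes and the replicate block within each subline were chosen after seeing the data. Counts are of genes at an adjusted p under 0.05 unless stated, and the cause of a change was not tested unless the setting itself gives it.

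The count with both replicates of every group was 2577 for dKO dNp63, 107 for TAp73, 2838 for dual and 957 for ITGB4-lo dNp63, each against its EV. It was 507 for the difference between the sublines, 64 for the departure from the sum, 2163 for TAp73 against dNp63, 48 for dual against dNp63, 2415 for dual against TAp73 and 3792 for dKO EV against ITGB4-lo EV. In that order, an adjusted p under 0.01 left 1533, 47, 1568, 493, 275, 22, 1179, 20, 1258 and 2135 genes by construction. A 2-fold minimum left 951, 70, 903, 293, 329, 48, 783, 25, 770 and 1110. The shared calls of dNp63 and TAp73 in dKO cells (87) became 36 and 53 at these thresholds, and those of dNp63 in both sublines (630) became 344 and 197.

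DESeq2 called 267 genes with TAp73, 30.71% of them higher against 48.6% by edgeR, and 115 for the departure from the sum. With no filter, over 38067 genes, the counts were 976 (25.82% higher) and 541 (59.33% higher against 28.12%), 838 for the difference between the sublines and 174 for dual against dNp63, and the calls shared by dNp63 and TAp73 were 474. With only the compared libraries in the fit the departure from the sum had 111 genes and dKO EV against ITGB4-lo EV 2147, 37.17% of them higher against 49.55%. Scaling by library size alone moved the share of higher calls from 41.13% to 49.79% for dNp63 and from 40.1% to 49.67% for dual. With a filter of 1 CPM in 2 libraries 3 lists were called with TAp73 in place of 7. With an estimated correlation camera called 0, 0, 0 and 3 lists in the 4 comparisons with EV, in place of 10, 7, 9 and 17.

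With the replicate number as a block, TAp73 had 363 calls (23.42% higher), the departure from the sum 111 (40.54% higher) and the calls shared by dNp63 and TAp73 were 191. With a block of its own in each subline the counts were 1151 for TAp73, 1763 for ITGB4-lo dNp63, 943 for the difference between the sublines, 457 for the departure from the sum, 3367 for TAp73 against dNp63, 151 for dual against dNp63 and 3829 for dual against TAp73. With the GC and length trend removed in that fit they were 988, 2839, 1676, 697, 4393, 304 and 5032, with 4705 for dKO dNp63, 5009 for dual and 6429 for dKO EV against ITGB4-lo EV. Calls shared by dNp63 and TAp73 were 555 and 565 in these fits, and those of dNp63 in both sublines 1043 and 1581. That last fit also called the WNT list downward (adjusted p 0.00255) and the ligand (0.00631) and proliferation (0.0476) lists upward with TAp73, and ended the interferon call in ITGB4-lo cells (0.0930). The single block ended the list calls of interferon genes with TAp73 (adjusted p 0.0667) and of wound genes with dual (0.0501), and moved no other count by over 1.5 times.

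With each library left out in turn the counts were 1584 to 3456, 32 to 1797, 1492 to 3657, 375 to 1179, 325 to 709, 22 to 593, 1152 to 2645, 9 to 63, 1133 to 2918 and 2781 to 3621, in the order above. The highest of these came without dKO EV replicate 1, except 63, which came without ITGB4-lo EV replicate 2. Shared calls were 25 to 1109 for dNp63 and TAp73 and 301 to 722 for dNp63 in both sublines. Lists called were 10 to 11, 2 to 11, 6 to 9 and 12 to 16. A group left with 1 library is assumed to vary like the other groups. With the GC and length trend removed TAp73 had 104 calls, 275 without dKO EV replicate 1 (25.82% higher) and 36 without replicate 2, and the calls shared with dNp63 were 205 and 29.

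Of 735 calls of named genes, 732 were kept with RLE factors, 720 with library size alone, 726 with no filter, 731 with the block, 735 with the block within each subline and 719 with the GC trend removed. DESeq2 kept 663 of 708, and 636 to 703 of 735 were kept with 1 library left out. None of these calls reversed in any of these settings. Of 569 results of named genes not called, 24 were called with the block, 86 with the block within each subline, 167 with that block and the GC trend removed, 46 with the trend removed alone, 88 with no filter and 19 of 563 by DESeq2. With 24017687 to 36974577 counts per library and 2 libraries per group, 1.5-fold changes were found for 22 of 50 simulated genes in dKO dNp63 against EV, so smaller changes can be missed.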

Other observations

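The tests of lists below were fixed before the data were examined. The chromosome windows, the genes with opposite effects and the comparison of ITGB4-lo calls with the dual libraries were chosen only after values were seen.

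The EV lines of the 2 sublines differed in many genes of the fixed lists, with subline and knockout confounded. Of 16 Notch genes 7 were higher in dKO EV and 2 lower (8 and 2 adjusted over the list alone), led by the ligand JAG2 (log2 3.88 ± 0.11) against DLL1 (-2.53 ± 0.38) and the receptor NOTCH3 (-1.25 ± 0.18). Of 11 stem cell markers 6 were lower and 1 higher (7 and 1 adjusted over the list alone), among them ALDH1A1 (38 against 2 counts, ratio 15.01, counting interval 3.88 to 128), the WNT effector TCF7L1 (-3.40 ± 0.36) and ITGA6 (-1.37 ± 0.11). Camera called the Notch list upward (adjusted p 0.00578) and the stem cell list downward (0.0179), each with an adjusted p = 0.356 with an estimated correlation. Calls of single genes in this paragraph and the next held by edgeR without each library in turn, and the list tests were not repeated that way.

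Other lists held members that differed both ways and were not called by camera. Of 24 mesenchymal genes 9 were higher and 6 lower (11 and 6 adjusted over the list alone; adjusted p 0.965), with POSTN (2.20 ± 0.37) and COL3A1 (1.94 ± 0.23) higher and COL6A3 (-2.75 ± 0.10) and DCN (-1.60 ± 0.31) lower. Of 25 interferon genes 5 were higher and 7 lower (5 and 8; 0.342), with IFIT1 at -2.97 ± 0.38 and OASL at -1.88 ± 0.29. Of 37 p53 family targets 2 were higher and 9 lower (3 and 9; 0.158), with GDF15 at 1.49 ± 0.14 and BTG2 at -1.49 ± 0.19. Of 23 WNT genes 6 were higher and 7 lower (7 and 9; 0.965), with TCF7 at 3.38 ± 0.32 and WNT7B at 3.05 ± 0.23. Basal genes differed both ways, KRT17 (3.87 ± 0.51) and S100A2 (2.41 ± 0.14) higher and IGFBP3 (-3.12 ± 0.28) and SERPINB5 (-2.41 ± 0.15) lower (2 higher and 4 lower of 14, both over all genes and adjusted over the list alone; 0.143). The squamous genes SPRR2D (4.59 ± 0.43) and PPL (4.08 ± 0.43), the wound gene PLAU (3.19 ± 0.17) and the EGFR ligand EPGN (3.86 ± 0.31) were higher and the ligand AREG (-1.92 ± 0.24) lower.

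Between the rescues, mesenchymal genes were higher with TAp73 than with dNp63 in 17 of 24 cases and lower in 2 (19 and 3 adjusted over the list alone; camera adjusted p 1.7e-15, and adjusted p = 0.0491 with an estimated correlation). Glycolysis genes were higher in 11 of 22 (13 adjusted over the list alone; 6.6e-06, and adjusted p = 0.177 with an estimated correlation). Dual cells had 11 of 25 interferon genes lower than TAp73 cells (12 adjusted over the list alone; 3.2e-04, and adjusted p = 0.0852 with an estimated correlation). They had 7 of 20 NF-kB genes lower and 1 higher (8 and 1 adjusted over the list alone; 0.0255, and adjusted p = 0.641 with an estimated correlation).

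Of the 507 genes whose dNp63 effect differed between the sublines, 343 were called in dKO cells alone, 34 in ITGB4-lo cells alone, 102 in both in the same direction, 19 in opposite directions and 9 in neither. Among the 19 were CDCP1 (log2 -0.88 in dKO and 0.67 in ITGB4-lo cells), PCDH1 (-1.08 and 1.06), TMEM158 (-0.86 and 0.70), OLAH (-0.58 and 1.12), the interferon-induced IFITM1 (-0.77 and 0.60), CADM3 (0.68 and -0.83) and RTN1 (0.49 and -0.52).

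Genes of the short arm of chromosome 17 were lower in dKO EV than in ITGB4-lo EV. In windows of 10 megabases of GRCh38 with at least 30 tested genes, 141 in number, the median log2 fold change had an SD of 0.13. It was -0.497 in the window from 0 to 10 megabases of chromosome 17, with 99.1% of 114 genes lower, and -0.436 from 10 to 20 megabases, with 86% of 50 genes lower. The lowest median of the other windows was -0.286. The windows of the same chromosome from 20 to 90 megabases lay the other way (0.14 to 0.256), and the highest of all, 0.256, was that from 30 to 40 megabases. Between the dNp63 libraries of the sublines the medians were -0.231 (91.2% lower) and -0.298 (90% lower). A window of chromosome 7 from 150 to 160 megabases was lower there (-0.363, 93.5% of genes lower), and 1 of chromosome 11 from 120 to 130 megabases was at -0.241, so the short arm did not stand apart in that comparison, and the windows of chromosome 17 from 20 to 90 megabases were at 0.252 to 0.33. No test of the cause was made.

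The genes that dNp63 raised in ITGB4-lo cells (415 without TP63) had a median log2 fold change of -0.155 in dual against dNp63 dKO cells, with 330 lower, and the 541 that it lowered had a median of 0.0949, with 358 higher.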
